A study of Arabidopsis thaliana with 30 samples.

How the data were processed

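RNA was measured by sequencing in hypocotyl explants of Arabidopsis thaliana. Etiolated seedlings of the Col-0 wild type and of the hsfa1abd-2 mutant were used at an age of 7 days, and their hypocotyls were cut. Explants were collected at 0, 0.5, 1, 3 and 24 h, about 50 per replicate, with 3 biological replicates per genotype and time. The 10 groups hold 30 libraries. The explants labelled 0 h also carry the label wounded, and no uncut or time-matched uncut seedlings were analysed here. At 0.5, 1 and 3 h, time since cutting therefore cannot be told apart from time of day. At 24 h, a full day after 0 h, it cannot be told apart from the age of the tissue.

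RNA was isolated with a Qiagen RNeasy plant kit and libraries were made with a stranded mRNA kit from Kapa, per the labels' protocols. Reads were handled with fastp and STAR on the TAIR10 genome, per the submitters' processing notes. The versions, the counting tool, its strand setting and the annotation are not given in the sources used here. The authors deposited 1 table of raw counts, whole numbers per feature and library, not normalized. Reads of near-identical paralogs, of overlapping genes and of antisense partners may be split or merged in it in ways that the sources do not state.

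The table has 36635 rows, each used as 1 feature, and its rows carry no gene identifier. No gene name was taken from the order of the rows, and no reference annotation was used. Features are given by number, counted from the first data row, and only 4 are named in this way. The gene lists fixed before the data were examined (among them heat shock factors, chaperones, wound regulators, hormone pathways, cell division, light, clock, and root, shoot apex and seed storage markers) could not be matched and were not tested. For the same reason the targeted HSFA1 genes could not be read in any library, and the genotype labels were checked only through the features that differed at 0 h.

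Counts were tested with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Features were kept by filterByExpr with the 10 groups, a minimum count of 10 and a minimum total of 15, which set a limit of 2.78 CPM at the median depth. This left 18526 tested features, which hold 99.8% of all counts. A further 10278 rows had no count in any library. Libraries were scaled by TMM, and all 30 were fitted in 1 quasi-likelihood model with 10 groups (robust estimateDisp and glmQLFit, then glmQLFTest). The biological coefficient of variation was 13.1%, with 20 residual degrees of freedom and a median of 12 prior degrees of freedom. Contrasts were each time against 0 h within a genotype, mutant against wild type at each time, and the difference between genotypes in the change from 0 h, tested at each time and jointly over 4 times. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Folds are log2, and a second count uses calls of at least 2-fold. Log2 CPM values use a prior count of 2, and the folds use edgeR's own default prior count. Each SE given for a fold is approximate, the size of the log2 fold divided by the square root of its F value.

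The planned rule for leading features took, per contrast, up to 4 higher and 4 lower ones by log2 fold among called features with at least 5 CPM in a compared group and replicates that do not overlap. Because the features carry no identifiers, these are given as ranges, and only 4 are given by number. They are the 2 most negative differences in change at 0.5 h and the 2 most positive at 24 h, and this narrower choice was made after their values were seen.

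The size of the response was measured per library as the mean log2 change from 0 h over features called at least 2-fold in the average of both genotypes, so that neither genotype chose the set. Genotypes were compared by a two-sided exact permutation test of 3 libraries against 3, which cannot go below p = 0.1. Changes per library subtract the mean of the genotype's 0 h libraries as a fixed value. Error in that mean is therefore in neither their SDs nor this test. Counts were also simulated 5 times with the measured genotype and time effects and no difference in response between genotypes. In all simulated counts each feature was drawn independently, so deviations that many features of a library share are left out. The tests were checked on simulated counts of 18526 features, with 200 changed per time. In the genotype contrast at 1 h, 86.4% of 4-fold changes, 50.7% of 2-fold changes and 29.9% of 1.5-fold changes were called. In the difference in change at 1 h these shares were 68.2%, 31.3% and 7.46%. For the genotype contrast at 24 h they were 83.3%, 64.2% and 22.4%, and for the difference in change at 24 h 66.7%, 37.3% and 4.48%.

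Total counts were 3164714 to 4296509 per library outside the wild-type 0.5 h replicate 1 library, with a median of 3643380. That library held 578179 counts, 15.9% of the median. A count of 3 equals 0.823 CPM at the median depth and 5.19 CPM in the shallow library. Counts are of reads without molecular identifiers, so counting intervals cover counting error only.

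Alternatives planned before the data were examined were DESeq2 size factors within edgeR, DESeq2 1.42.0, no filter, a stricter filter of 5 CPM in 3 libraries, fits of the compared groups alone, the replicate number as a block, leaving out each library, and no fold minimum for the dependence counts. Leaving out the shallow library, leaving out 5 abundant features and all alternatives for the response size were added after the data were seen. Alternatives that need gene identities (organelle genes left out, genes near the 3 lesions left out, other list tests) were not run.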

Results

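The hsfa1abd-2 mutant is named for HSFA1A, HSFA1B and HSFA1D, class A heat shock factors that start the transcriptional response to heat in Arabidopsis. Transcript counts were obtained from dark-grown hypocotyl explants of the wild type and of this mutant at 0, 0.5, 1, 3 and 24 h after cutting, with 3 biological replicates in each of the 10 groups. The comparisons ask how transcript levels changed after wounding, how the genotypes differed at each time, and whether the response to wounding differed between them. The wild-type 0.5 h replicate 1 library held 578179 counts and the other libraries 3164714 to 4296509. That library had counts for 18223 features, against 20842 to 21518 in the others. Replicates of a group correlated at r = 0.923 to 0.982 in log2 CPM across features, with no value under 0.957 outside 0.5 h. All replicate pairs differed by more than sampling noise, with chi-square values of 1.77 to 16.9 per degree of freedom. Rows of the count table carry no gene identifiers, so results are given for features, grouped by direction, size and timing.

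On the first and second principal components the libraries grouped by time after wounding. The first component of log2 CPM held 34.1% of the variance and the second 24.4%. The first was positive in the 0.5, 1 and 3 h libraries, negative in the 0 h libraries and lowest in the 24 h libraries. The second rose from 0 to 3 h in both genotypes and was lower again at 24 h.

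**Figure D1:**
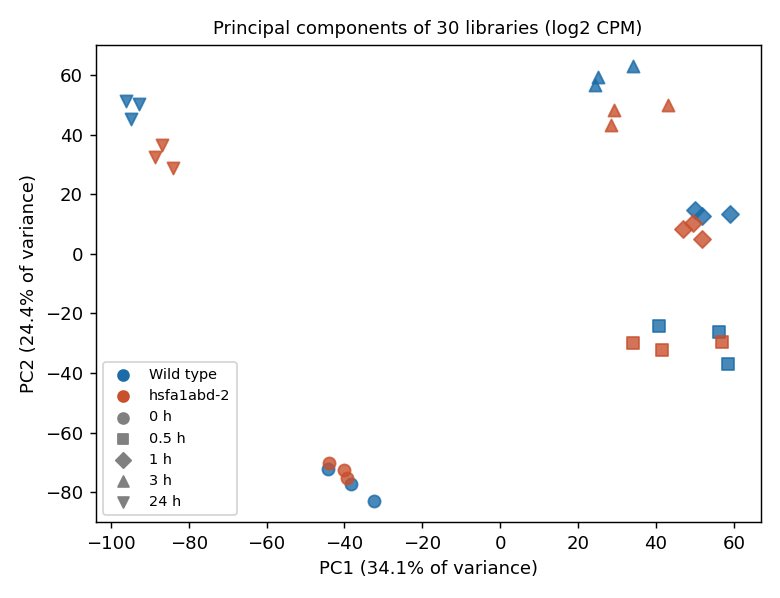
Principal components of log2 CPM in 30 libraries, with the first component (34.1% of the variance) on the x axis and the second (24.4%) on the y axis; each point is 1 library, coloured by genotype and shaped by time. The genotypes lie close together at 0 h, and the wild-type 24 h libraries sit above the mutant ones on the second component.

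In the wild type, changes of at least 2-fold after wounding were mostly rises at first, and the share of falls grew later. At 0.5 h, 1728 features were at least 2-fold higher than at 0 h and 681 at least 2-fold lower. These numbers grew to 2302 and 1331 at 1 h, to 2657 and 1655 at 3 h, and to 2888 and 2500 at 24 h. Rises thus made up 71.7% of the 2-fold changes at 0.5 h and 53.6% at 24 h. With no fold minimum, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4319, 7240, 8660 and 10208 of the 18526 tested features at the 4 times. Rises were 60.1%, 51.0%, 54.0% and 54.4% of these, so their share fell steadily only among 2-fold changes. The leading increases at 1 h lay between 9.90 and 12.14 on the log2 scale and the leading decreases at 24 h between -8.23 and -9.80. Folds of this size are measured against groups near 0 counts, so they depend on the prior count and are no bound.

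The early and late responses of the wild type overlapped in part. Of the features that rose at least 2-fold at 0.5 h, 1418 of 1728 (82.1%) were also up at 1 h, but 590 (34.1%) were up at 24 h and 108 were at least 2-fold down at 24 h. Between 3 and 24 h, 1202 of 2657 rises (45.2%) were shared. Independent lists would share 215 features between 0.5 and 1 h, 269 between 0.5 and 24 h and 414 between 3 and 24 h. Unchanged groups simulated 5 times against these controls gave 0 shared features by the same edgeR test, which is chance with no effect and leaves out the real changes. All of these contrasts use the same 3 libraries at 0 h, so part of the excess may come from the shared controls. Over the time course 5046 features rose at least 2-fold at 1 or more times, of which 731 reached their highest fold at 0.5 h, 891 at 1 h, 1439 at 3 h and 1985 at 24 h. Of the 3773 features that fell, 2120 (56.2%) reached their lowest fold at 24 h. Sustained changes were fewer, with 510 features up and 225 down by at least 2-fold at all 4 times.

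In the hsfa1abd-2 mutant most of the wound response was present. At 0.5, 1, 3 and 24 h, 1681, 2228, 2576 and 2181 features were at least 2-fold higher than at 0 h, and 560, 973, 1377 and 1925 at least 2-fold lower. In all, edgeR's quasi-likelihood test called 4251, 6490, 7902 and 8869 features at these times. The changes in the mutant correlated with those in the wild type across called features at r = 0.928, 0.933, 0.930 and 0.895, from libraries that the genotypes do not share. Features are not independent replicates, so these coefficients describe the profiles only. Opposite calls in the genotypes were rare, with 3, 1, 12 and 37 features at the 4 times.

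**Figure D2:**
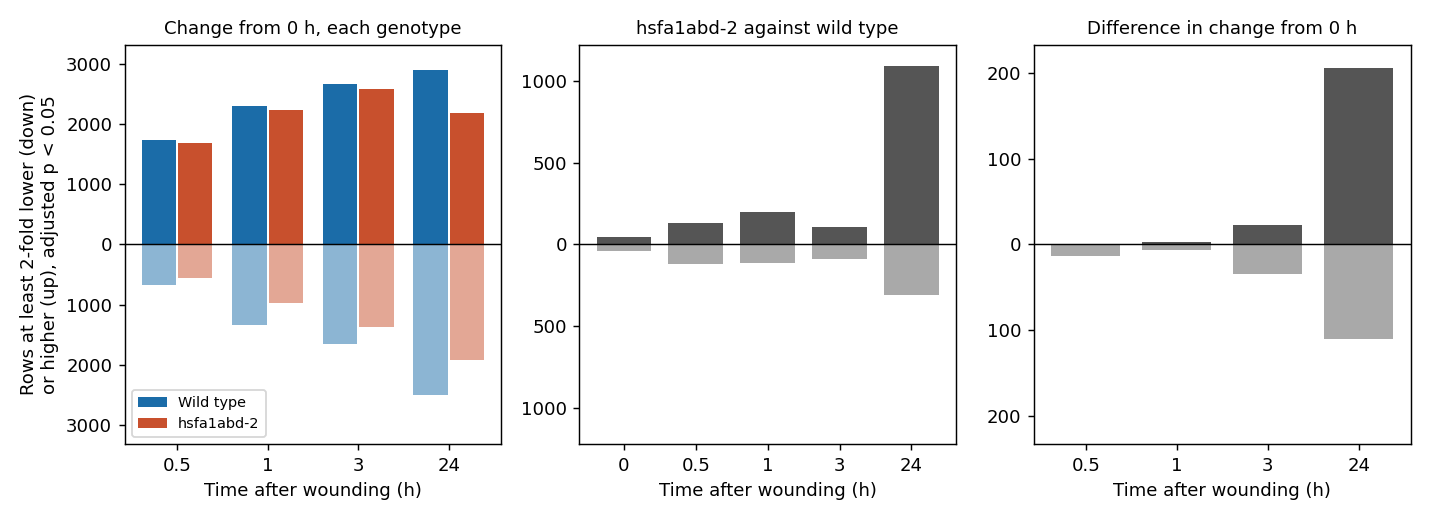
Numbers of features called at an adjusted p under 0.05 with a change of at least 2-fold, higher above 0 and lower below it, on the y axis (a separate scale per panel) against time after wounding on the x axis. The left panel counts changes from 0 h in each genotype, the middle panel mutant against wild type, and the right panel the difference between genotypes in the change from 0 h. At 24 h the mutant had 2181 rises and 1925 falls against 2888 and 2500 in the wild type, and 1092 features were higher in the mutant against 311 lower.

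The mean size of the shared response was smaller in the mutant at each time. Features that rose at 24 h changed by 1.77 ± 0.0363 (SD, n = 3) on the log2 scale in the wild type and by 1.46 ± 0.0432 (SD, n = 3) in the mutant, 82.3% of the wild-type value. Those that fell changed by -1.86 ± 0.0547 (SD, n = 3) and by -1.55 ± 0.0767 (SD, n = 3). No library of one genotype overlapped those of the other, and the exact permutation test gave p = 0.1 for each, the smallest possible with 3 against 3 (adjusted p = 0.133 over 8 such tests). At 3 h the rises were 2.24 ± 0.0908 and 2.11 ± 0.116 (SD, n = 3 each, exact permutation p = 0.3), and at 0.5 h 2.23 ± 0.151 and 2.07 ± 0.206 (exact permutation p = 0.4), with libraries that overlapped. Libraries of the genotypes did not overlap, with the same exact permutation p = 0.1 as at 24 h, for rises at 1 h (mutant minus wild type -0.143) and for falls at 0.5, 1 and 3 h (0.237, 0.143 and 0.123). Before 24 h these sizes depend on single libraries. The difference in falls at 0.5 h was 0.425 without wild-type 0.5 h replicate 3, 0.104 and 0.151 without mutant 0.5 h replicates 2 and 3 (exact permutation p = 0.6 and 0.4), and overlapped without mutant 0 h or 0.5 h replicate 1 (0.172 and 0.204, exact permutation p = 0.3 each). That in falls at 1 h was 0.063 without mutant 0 h replicate 2 and 0.084, 0.077 and 0.05 without mutant 1 h replicates 1, 2 and 3, and that in rises at 1 h was -0.218 without wild-type 0 h replicate 1. The falls at 1 h also gave 0.081 with 5 abundant features left out and 0.084 with no filter. That in falls at 3 h was 0.079 and 0.063 without mutant 3 h replicates 1 and 3 (exact permutation p = 0.2 each) and that in rises at 3 h -0.061 without mutant 3 h replicate 2. For rises at 0.5 h it was -0.104 and -0.269 without wild-type 0.5 h replicates 2 and 3 and -0.302 and -0.077 without mutant 0.5 h replicates 2 and 3. An orthogonal fit (first principal axis) of the mutant change against the wild-type change gave a slope of 0.807 at 24 h and 0.910 to 0.930 at the earlier times. Counts simulated without a difference in response, with features drawn independently, gave 0.993 to 1.

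**Figure D3:**
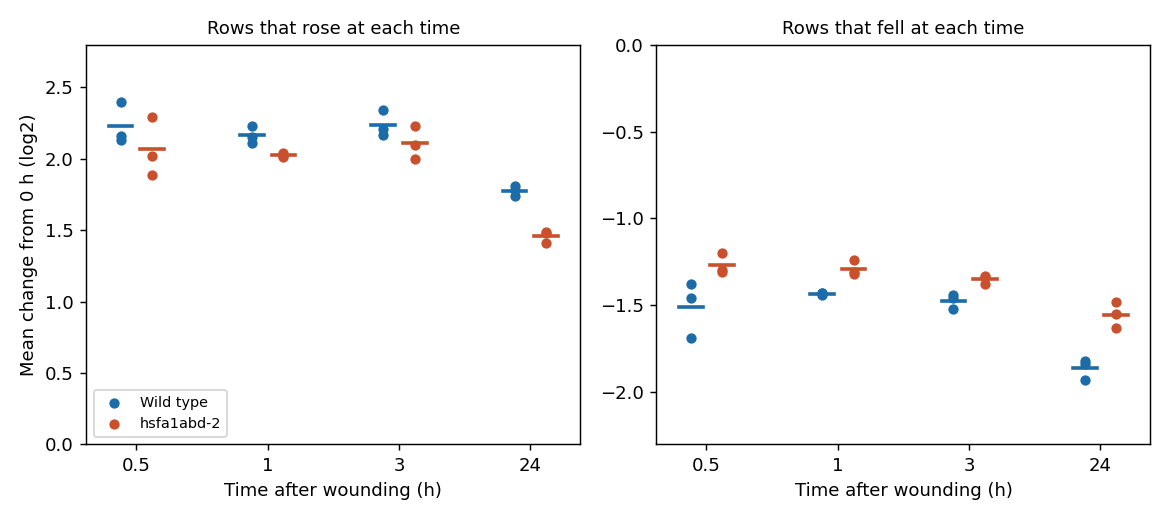
Mean change from 0 h on the log2 scale (y axis) over features that rose (left) or fell (right) at least 2-fold in the average of both genotypes, against time after wounding (x axis); points are libraries and bars the means of 3. At 24 h the rises averaged 1.77 in the wild type and 1.46 in the mutant, with no overlap between libraries.

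At 0 h the genotypes differed in few features, and most of these were lower in the mutant. Of 346 called features, 268 were lower and 78 higher in hsfa1abd-2, and 40 and 45 of these differed at least 2-fold. The median size of a called difference was 0.689 on the log2 scale. The 78 higher and 268 lower features also parted the genotypes in the 24 libraries of later times, in which the mean of the higher ones minus that of the lower ones was -1.37 to -0.44 in the mutant and -3.37 to -1.70 in the wild type. The count at 0 h depends on single libraries, with 74, 83, 109 and 121 calls without mutant replicate 2, mutant replicate 3, wild-type replicate 3 and wild-type replicate 2. In fits of the 6 libraries alone it was 912.

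At 0.5, 1 and 3 h the mutant differed from the wild type in 680, 1117 and 370 features by edgeR's quasi-likelihood test. At 0.5 h 285 of these were higher and 395 lower in the mutant, at 1 h 567 and 550, and at 3 h 193 and 177. Differences of at least 2-fold numbered 130 higher and 122 lower at 0.5 h, 198 and 112 at 1 h, and 104 and 90 at 3 h. The leading differences at 3 h were increases of 6.18 to 7.74 and decreases of -7.42 to -11.21 on the log2 scale, again against groups near 0 counts. Lists of features that differed at different times overlapped, with 14.6% to 72.3% of the earlier list shared. Of the 395 features lower at 0.5 h, 217 (54.9%) were also lower at 1 h, against 11.7 for independent lists, and 270 of the 550 lower at 1 h (49.1%) were lower at 24 h, against 56.4. Of the 567 higher at 1 h, 83 (14.6%) were higher at 3 h, against 5.91. No library is shared between these times, but all contrasts use 1 fit with a common estimate of each feature's spread. Abundant or steady features are easier to call at any time, so independent lists are a low baseline. Part of the excess may come from this. The count at 0.5 h was 157 without wild-type replicate 2, 1212 without wild-type replicate 3, and 362, 1984 and 227 without mutant replicates 1, 2 and 3. At 1 h it was 349 and 504 without wild-type replicates 1 and 3 and 422 and 380 without mutant replicates 2 and 3; at 3 h it was 160 and 237 without wild-type replicates 1 and 2 and 200 and 560 without mutant replicates 2 and 3. Fits of the 6 compared libraries alone gave 161, 2870 and 145.

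At 24 h the genotypes differed in 3863 features, 20.9% of those tested. The mutant was higher in 1962 and lower in 1901, but differences of at least 2-fold were mostly increases, with 1092 higher and 311 lower (77.8% higher). The 1092 features with higher levels in the mutant included many that had declined in the wild type. Their median level at 24 h was 7.75 CPM in the wild type and 19.5 CPM in the mutant. Of these, 598 had fallen from 0 h in the wild type and 189 in the mutant, and 236 had risen in the mutant. Of all 18526 tested features, 4650 had fallen in the wild type and 3941 in the mutant, and 4928 had risen in the mutant. Among the 311 lower features, 222 had risen in the wild type and 110 in the mutant, with medians of 5.45 CPM at 0 h, 14.9 CPM at 24 h in the wild type and 5.84 CPM in the mutant. Of all tested features, 5558 had risen in the wild type. Both sets were chosen in the same 24 h libraries that give these falls and rises. That choice favours such imbalances, so the counts describe the sets and do not test them. Over all 3863 features, 2598 (67.3%) differed against the sign of the change from 0 h averaged over both genotypes, compared with 58.8% of all tested features. That averaged change was not required to be called or to have the same sign in each genotype. The count was 2568 without wild-type replicate 2 and 2508 without mutant replicate 3.

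Tested directly, the response to wounding differed between genotypes in 532 features by the joint edgeR quasi-likelihood test over 4 times. The change from 0 h differed in 15 features at 0.5 h, each of them with the lower change in the mutant, in 11 at 1 h (8 lower and 3 higher), in 89 at 3 h (41 and 48) and in 584 at 24 h (268 and 316). DESeq2 called 26, 24, 150 and 874 features at these times and 978 jointly, with 1 of its 26 at 0.5 h higher in the mutant. Fits of the compared libraries alone gave 41, 36 and 1645 at 1, 3 and 24 h, and the fit without the shallow library gave 7 at 1 h. Of these counts, that at 0.5 h stayed within 1.5 times when any single library was left out (13 to 20). At 24 h the count was 248 and 386 without wild-type 0 h replicates 2 and 3, 386 without mutant 0 h replicate 3, 262 without wild-type 24 h replicate 2, and 339 and 256 without mutant 24 h replicates 2 and 3. At 3 h it was 25 and 43 without wild-type 0 h replicates 2 and 3, 55, 35 and 42 without mutant 0 h replicates 1, 2 and 3, 44 and 42 without wild-type 3 h replicates 1 and 2, and 40 without mutant 3 h replicate 2. At 1 h it was 7 and 6 without wild-type 0 h replicates 2 and 3 and 7 without mutant 0 h replicate 2. The joint count was 321 and 219 without wild-type 24 h replicates 1 and 2, 279 and 204 without mutant 24 h replicates 2 and 3, 898 without mutant 0.5 h replicate 2 and 911 without mutant 3 h replicate 2.

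Among features that rose at least 2-fold in the wild type, 11 of 1728 were called with a smaller rise in the mutant at 0.5 h, 7 of 2302 at 1 h, 34 of 2657 at 3 h and 191 of 2888 at 24 h. Called or not, the change was smaller in the mutant for 72.7%, 71.2%, 65.9% and 85.9% of these wild-type rises, against 56.0%, 56.3%, 55.5% and 57.9% in counts simulated without a difference in response. Features called up in the mutant and called with a smaller rise in the wild type numbered 10 at 3 h and 18 at 24 h. At 24 h the falls showed the same asymmetry, with 209 of 2500 wild-type falls smaller in the mutant and 9 of 1925 mutant falls smaller in the wild type. Counts simulated 5 times without a difference in response gave 0 smaller rises in the mutant at each time by the same edgeR test. Features were drawn independently in these counts. Deviations shared by many features of a library, such as those at 0 h, are therefore not in this baseline and could add to the asymmetry. Fits of the compared libraries alone gave 32, 22 and 440 smaller rises at 1, 3 and 24 h, and DESeq2 gave 19 and 14 at 0.5 and 1 h. At 24 h 34 of the 191 features were not called up in the mutant, at 3 h 23 of 34 and at 0.5 h 8 of 11. The 191 features at 24 h became 78 and 124 without wild-type 0 h replicates 2 and 3, 104 without wild-type 24 h replicate 2, and 108 and 82 without mutant 24 h replicates 2 and 3. The 34 at 3 h became 18 without wild-type 0 h replicate 2, 20 without mutant 0 h replicate 1 and 22 without mutant 3 h replicate 2, and the 7 at 1 h became 4 without wild-type 0 h replicate 2 or 3, wild-type 1 h replicate 1 or mutant 0 h replicate 1.

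The 15 features with a smaller early change, chosen by that test in the same libraries, were ones that rose rapidly in the wild type and on average stayed near the 0 h level in the mutant. All 15 were called up in the wild type at 0.5 h, with a median change of 1.96 on the log2 scale, while 3 were called up in the mutant, where the median change was -0.0612. Their mean level in the wild type went from 5.18 ± 0.0561 to 7.42 ± 0.142 log2 CPM between 0 and 0.5 h and was 7.54 ± 0.229 at 3 h (SD, n = 3). In the mutant it was 4.35 ± 0.0397 at 0 h, 4.33 ± 0.101 at 0.5 h and 4.39 ± 0.0785 at 3 h (SD, n = 3). At 3 h, 13 of the 15 again had a smaller change in the mutant, although both contrasts use the same libraries at 0 h, and at 24 h 1 of the 15 did. Of the 15, 7 were already lower in the mutant at 0 h, and 6 belong to the 40 features that were lower at all 5 times. Feature 21556 had 14 counts over the 3 libraries at 0 h in each genotype, and at 0.5 h 669 in the wild type and 43 in the mutant. At 3 h it stood at 42.7 ± 7.15 CPM in the wild type and 1.67 ± 0.957 CPM in the mutant (SD, n = 3). Its change at 0.5 h differed by -4.31 on the log2 scale (approximate SE 0.65, adjusted p = 0.000474 by edgeR's quasi-likelihood test). Feature 14078 rose from 7.24 ± 0.859 to 68.9 ± 5.95 CPM in the wild type, against 2.11 ± 1.58 and 0.903 ± 0.622 CPM in the mutant (SD, n = 3), a difference in change of -4.54 (SE 0.74, adjusted p = 0.00216). The call of feature 14078 was lost without mutant 0 h replicate 1 (-3.67, adjusted p = 0.25) and that of feature 21556 without mutant 0 h replicate 2 (-3.86, adjusted p = 0.054).

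At 24 h the features with the most positive difference in change were ones that almost vanished in the wild type. Feature 31335 fell from 31.0 ± 16.7 CPM at 0 h to 0.276 ± 0.283 CPM at 24 h in the wild type and from 30.7 ± 10.5 to 6.10 ± 3.34 CPM in the mutant (SD, n = 3). At 24 h it had 75 counts in the mutant and 3 in the wild type, a ratio of 24.5 with an exact 95% counting interval of 8.06 to 121, and its change differed by 4.35 (SE 1.00, edgeR adjusted p = 0.017). Feature 25255 had 11 counts in the mutant and 1 in the wild type at 24 h, a ratio of 10.8 with an interval of 1.57 to 464 (difference in change 3.87, edgeR adjusted p = 0.0262). Both calls are near the detection limit. That of feature 31335 was lost without wild-type 24 h replicate 2 (adjusted p = 0.0758) or mutant 24 h replicate 3 (0.0607) and in a fit of the compared libraries (0.122). That of feature 25255 was lost without 5 different libraries, namely wild-type 0 h replicate 2 (0.0573), each of wild-type 24 h replicates 1 and 3 (0.0876 and 0.0715), mutant 0 h replicate 1 (0.0508) and mutant 24 h replicate 3 (0.222).

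A set of 40 features was lower in the mutant at all 5 times, and 11 were higher at all 5. The 40 lower features had a mean change from 0 h in the wild type of 0.990 ± 0.0837 on the log2 scale at 0.5 h, 1.03 ± 0.104 at 3 h and -0.0129 ± 0.0848 at 24 h (SD, n = 3). In the mutant the same changes were 0.098 ± 0.0953, 0.236 ± 0.0576 and -0.15 ± 0.0245 (SD, n = 3). These features were chosen for being lower in the mutant in the same libraries, so the means describe the set and do not test it. At 0.5 h 26 of the 40 were called up in the wild type and 7 in the mutant, and at 24 h 16 and 10. A smaller change in the mutant was called by edgeR's quasi-likelihood test in 6, 3, 11 and 0 of the 40 at 0.5, 1, 3 and 24 h. At an unadjusted p under 0.05 these counts were 22, 15, 18 and 8, and by DESeq2 13, 7, 11 and 1. The 11 higher features were 3 to 4 log2 units higher in the mutant, with medians of 2.98 at 0 h and 4.03 at 24 h, and each differed at least 2-fold at each time. Wild-type libraries held only 7 to 166 counts over the 11 features, so these folds are measured near 0 counts and are no bound. Over all tested features, not only these sets, levels of 20 lower and 4 higher features did not overlap between the 15 libraries of each genotype. The set of 40 shrank to 24 without mutant 0 h replicate 2. The set of 11 was 2 in fits of the compared libraries, 7 with no filter, 2 without wild-type 0 h replicate 3, 4 without wild-type 0 h replicate 1 or without mutant 0 h replicate 1 or 3, and 7 without wild-type 3 h replicate 1 or 2, wild-type 24 h replicate 1 or mutant 0 h replicate 2.

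**Figure D4:**
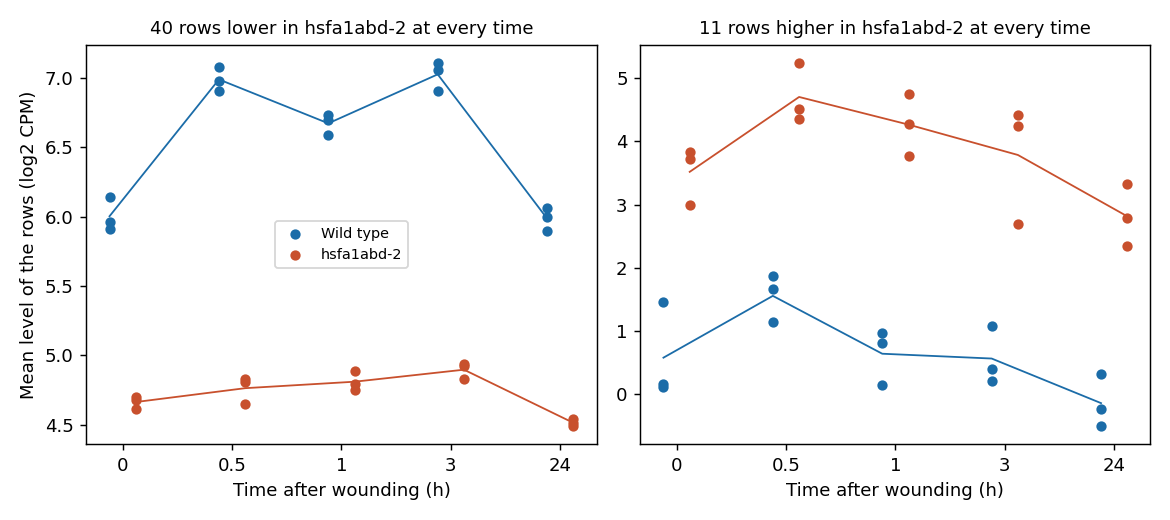
Mean log2 CPM (y axis) of the 40 features lower (left) and the 11 features higher (right) in the mutant at all 5 times, against time after wounding (x axis, times evenly spaced); points are libraries and lines join the means of 3. In the wild type the mean of the 40 features was 0.990 higher at 0.5 h than at 0 h and -0.0129 from it at 24 h; 26 of the 40 were called up at 0.5 h and 16 at 24 h.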

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

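The comparison of single 0.5 h libraries with the later change and the test of a scaling error behind all calls were chosen after the results were seen, the conditions that leave the tests of linked DNA and of scaling undecided were set after their values were seen, and the number of reshuffled arrangements was raised from 40 to 100 after the first 40 had been counted. The change from 0 h differed between genotypes, by a direct test of the difference, in 15 features at 0.5 h, 11 at 1 h, 89 at 3 h, 584 at 24 h and 532 features jointly. Genotype labels were reshuffled within each time in 100 arrangements, the real one included. At 3 h 1 of 100 reached the real count (highest other 3) and at 1 h 2 (highest other 1012). At 0.5 h 4 did (highest other 271), so each share was under 0.05. Arrangements that mix the genotypes place their difference in the spread within groups, which can lower their counts. These shares therefore cannot exclude chance for a difference in response. At 0.5 h an arrangement with the genotypes mixed at both 0 and 0.5 h gave 26 calls. The first 40 arrangements gave 1, 1 and 2 at 3, 1 and 0.5 h, and 2 of 40 at 0.5 h is not a share under 0.05. At 24 h 7 of 100 reached the real count (highest other 2764) and for the joint test 6 (highest other 2399), so these arrangements did not exclude chance, nor did the first 40 (3 and 2). Counts simulated 5 times with the measured genotype and time effects and no difference in response gave 0 or 1 calls at 24 h and 0 jointly. Their features were drawn independently, so they leave out deviations that many features of a library share. Counts several times the real one point to a structure of the samples. The highest others at 0.5, 1 and 24 h kept the genotypes apart at both times compared but exchanged their labels at 1 of them, and all 6 other arrangements at 24 h kept the 24 h libraries apart by genotype, so they still held the genotype difference.

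For contrasts of 3 libraries against 3, fitted alone, 10 splits are too few for a share under 0.05. The real splits called 3611 to 10218 features in wild type and 3287 to 9395 in the mutant between times, with 0 as the highest other. Between genotypes they called 912 at 0 h (highest other 1), 2870 at 1 h (0), 145 at 3 h (6) and 4415 at 24 h (0). At 0.5 h the real split called 161 and 2 of the 10 splits reached that. The highest other called 1385, with wild-type replicates 1 and 2 and mutant replicate 2 on one side, which points to a structure of the samples other than genotype.

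The first pattern is the broad difference between genotypes at 24 h, with 3863 features. A common scaling factor as the source of all calls is argued against, since it would move all features one way and 49.2% of the calls were lower. TMM centres the folds, so this near-even split cannot show whether a scaling error added to real differences. For the excess of higher calls among 2-fold calls scaling stays open: other size factors moved that share by 1.8 percentage points (from 77.8% to 76.0%), but the median of all features by only -0.0147 log2, too little to decide. A single aberrant library is argued against, since the lowest count without 1 of the 6 libraries was 2508. For a smaller response in the mutant, at least 60% of called features had been asked, before the share was computed, to differ against the mean change of both genotypes. The share was 67.3%, but over all tested features it was already 58.8%, so passing this bound decides little. A smaller response may account for part of the pattern only, since 746 higher and 519 lower features differed the other way. A slower course of the same response and a different outcome at 24 h stay open.

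The second pattern is the difference at 0.5 and 1 h. At 1 h the genotype difference did not follow the net change from 0.5 to 3 h (r = 0.0144 across all features and -0.0415 across called ones). The r across all features was under the bound of 0.1 set before the test, which counted against a difference in effective harvest time. No delay was simulated, so the r that a lag would give is not known, and a timing difference at 1 h stays open. At 3 h the genotype difference ran against the change from 1 to 24 h (r = -0.128 and -0.291). At 0.5 h the corresponding r was -0.115 across all features and -0.228 across called ones, between the bounds of 0.1 and 0.5 set before the test, so a small difference in timing cannot be told apart from genotype. The shallow wild-type library is argued against as the sole cause, since the count was 459 without it. Replicates caught at different points of the response remain possible, since the deviations of single 0.5 h libraries followed the change from 0 to 1 h with r values that spanned 0.232 within the mutant.

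The third pattern is the set of 346 features that differed at 0 h. Genotypes mixed or exchanged in some libraries or times are argued against, though an exchange in all libraries alike would not be seen, because the lowest mutant library of the later times lay 0.327 log2 units above the highest wild-type library on the score of these features. Linked DNA from another parent, carried along with the mutated loci, cannot be told apart from an effect of the mutations, and a genotype effect present before or at cutting stays open. The densest window of 200 features held 13 of the called ones, equal to the 95th percentile of shuffled orders (13), and lists of equal size changed by wounding at 1 and 24 h held 9 and 12, so this order may not follow the genome. The 11 features higher at all 5 times had 3 in a window, above the shuffled 95th percentile of 2 but under the highest shuffle of 5.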

How the results depend on the processing

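The alternatives without the shallow library or without 5 abundant features, and all those for the response size, were chosen after seeing the data. Of 24 counts, all stayed within 1.5 times of the reported value with DESeq2 size factors, the stricter filter and the 5 features left out. Those size factors moved the median of all features by -0.0335 log2 in the contrast it moved most, so they say little about scaling. With no filter 23 did, the exception being 7 features higher in the mutant at all 5 times, and without the shallow library 23 did, the exception being 7 features with a different change at 1 h. The replicate numbers showed no pairing of the samples on average. The 135 same-numbered pairs had a mean r of 0.0011 between their deviations (13 above 0.1), and 270 other pairs -0.000515 (27 above 0.1). Of 30 libraries, 14 correlated best with their own number among the 3 numbers, a share that was not tested. With the replicate block all 24 counts stayed within 1.5 times, with 3787 features between genotypes at 24 h, 574 with a different change at 24 h and 488 jointly. DESeq2 gave more interaction calls: 26, 24 and 150 at 0.5, 1 and 3 h, 978 jointly, and 19 and 14 wild-type rises smaller in the mutant at 0.5 and 1 h; the cause was not tested. Fits of only the compared libraries, which estimate the spread from fewer samples, moved 11 of 23 counts: 912, 161, 2870 and 145 between genotypes at 0, 0.5, 1 and 3 h, 41, 36 and 1645 differences in change at 1, 3 and 24 h, 32, 22 and 440 smaller rises in the mutant at these times, and 2 features higher at all 5 times. With no fold minimum the 4 counts of smaller rises stayed within 1.5 times.

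Leaving out each library moved 63 of 264 counts by over 1.5 times. The counts against 0 h within a genotype were not among them, with 3310 to 4134, 6168 to 6505, 7653 to 8043 and 9187 to 9700 in wild type and 3597 to 3985, 5566 to 5883, 7060 to 7629 and 7658 to 8096 in the mutant. Between genotypes the ranges were 74 to 279 at 0 h, 157 to 1984 at 0.5 h, 349 to 1039 at 1 h, 160 to 560 at 3 h and 2508 to 3411 at 24 h. Differences in change ranged over 13 to 20, 6 to 14, 25 to 98 and 248 to 653 at the 4 times and 204 to 911 jointly. Smaller rises in the mutant ranged over 10 to 16, 4 to 9, 18 to 46 and 78 to 234. Features higher or lower at all 5 times numbered 2 to 16 and 24 to 48. Fewer samples reduce these counts by construction, but rises such as 1984 at 0.5 h without mutant replicate 2 were not explained. The response size kept its direction in all 96 fits that left out a library and in all 5 other settings, with -0.414 to -0.283 for rises and 0.239 to 0.336 for falls at 24 h. At 0.5, 1 and 3 h the ranges were wider for their size, with -0.302 to -0.077, -0.218 to -0.124 and -0.192 to -0.061 for rises and 0.104 to 0.425, 0.05 to 0.177 and 0.063 to 0.158 for falls. Among the 5 other settings the falls at 1 h moved by over 1.5 times, to 0.081 without the 5 features and 0.084 with no filter; the cause was not tested. The 4 named features lost their call in 9 of 48 such fits and 1 fit of the compared libraries, and none changed direction in the fits that gave a value; DESeq2 gave no adjusted p for feature 25255. Depth limits the low features most, since a count of 3 stands for 5.19 CPM in the shallow library. Alternatives without organelle genes or without genes near the lesions, and the list tests, were not run because the features carry no identifiers.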

Other observations

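The comparisons in this part and their limits (r of 0.9 and 0.8, shares over 4%) were chosen after the values were seen. A group of 5 abundant features varied together over the 30 libraries (r of at least 0.912 with the leading one, the next feature at 0.613). They took 0.685% to 1.41% of the counts in wild-type libraries and 0.532% to 8.11% in mutant libraries. Shares over 4% occurred in 4 libraries, mutant 0 h replicates 2 and 3 (6.83% and 5.47%), mutant 0.5 h replicate 1 (5.08%) and mutant 1 h replicate 1 (8.11%), while the other 26 libraries reached at most 1.77%. The leading feature alone ranged from 0.401% to 6.28%. What these features are is not known here, and leaving them out gave 250 in place of 346 features between genotypes at 0 h and 3996 in place of 3863 at 24 h.

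The 11 features higher in the mutant at all 5 times also varied together between replicates. Their deviations from the group means had a mean pairwise r of 0.762 in mutant libraries, against a 95th percentile of 0.0897 in 1000 lists of matched expression in the same libraries, and of 0.345 in wild-type libraries, which held only 7 to 166 counts over the 11 features, and their SD within a mutant group averaged 0.672 log2 units. The 40 features lower at all 5 times had a mean pairwise r of 0.0148 in mutant libraries, with a 95th percentile of 0.0393, an SD of 0.279, and a mean pairwise r of 0.158 in wild-type libraries, for which no random lists were drawn. Summed over the 11 features, mutant libraries held 74.0 to 678 CPM and wild-type libraries 1.92 to 64.0 CPM, the highest of these in the shallow library and the next, 45.4 CPM, in 0 h replicate 2. A further 92 features followed the mean of the 11 at r of at least 0.8 among mutant libraries, a number reached by 3 of 100 shuffles within groups.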
